A study of Mus musculus with 60 samples.

How the data were processed

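The series measured gene expression in fetal mouse brain on Affymetrix Mouse Gene 1.0 ST arrays. Pregnant mice received chlorpyrifos oxon (CPO), the active form of the insecticide chlorpyrifos, from gestational day 6 to day 17, and the fetal brains were collected on day 18. RNA of the fetal brains of 1 dam was pooled and put on 1 array, so the dam is the replicate. Dams were drawn at random after those with outlying brain acetylcholinesterase activity had been left out, per the series description. The labels give 12 groups of 5 arrays: wild type (WT), Pon1 knockout (KO), and mice with a human PON1 transgene of the Q192 form (Q-tg) or the R192 form (R-tg), each with a control dose of 0 and a pair of CPO doses. Doses are in mg per kg of body weight and day (mg/kg/d). KO received 0.50 or 0.75, and the other genotypes received 0.75 or 0.85.

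The deposited values are log2 signals made by the authors with RMA, per the submitters' processing notes, which name the oligo package under R 2.15.1. They were used as deposited, with no further normalization. The table holds 28858 transcript clusters (the array's rows, usually 1 per gene) on 60 arrays, with values from 2.1 to 14.04. GEO's platform annotation gave exactly 1 gene symbol for 21789 of them, several for 1621 and none for 5448. The 21789 were tested, and they name 19938 genes, 999 of them through more than 1 transcript cluster. Of the 21789, 21698 were found by gene number in the GRCm38.p6 gene table, which was used for names and neighbours alone. The number of arrays limits the precision.

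Groups were compared with limma 3.58.1 in R 4.3.3. One model with the 12 labelled groups was fitted to all 60 arrays, and 21 contrasts were taken from it with moderated statistics. They were 8 contrasts of a CPO dose against dose 0 within a labelled genotype, 2 averages of these over genotypes, 4 contrasts between genotypes at dose 0, and 7 differences of the CPO response between genotypes. Tests were 2-sided, p-values were adjusted by Benjamini-Hochberg over the 21789 transcript clusters of a contrast, and 0.05 was the threshold. A log2 difference is given with its standard error (SE) from this model.

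The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule names, in every contrast, Pon1, Pon2, Pon3, Ache and Bche, the genes that pass (at most 10 in each direction) and, where fewer than 10 pass, the 10 with the smallest p, given as values and not as changes. Predicted genes and small RNA genes gave way to the next named gene where their symbol had a set form, such as Gm with a number, Rik, LOC or Mir. Rprl2 and AF067061, whose symbols have other forms, stayed. Of a gene list that is described, the 4 measured members with the largest absolute log2 difference are given. Any other gene that is named was chosen after its values were seen. A transcript cluster was called dim where its mean was below 6.54, the 95th percentile of 1035 olfactory receptor transcript clusters, which left 15611 above that level.

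There were 42 gene lists with 1106 entries, of which 1009 were measured. camera tested 41 of them with its preset inter-gene correlation of 0.01 over 19938 genes (the brightest transcript cluster of each), with adjustment over the lists of a contrast. The list of sex linked genes was described and not tested. The same tests were run with the correlation estimated from the data and with fry. Counts of list members were also adjusted over the list alone.

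Log2 differences at CPO 0.75 were correlated across genes between labelled genotypes. They were compared with 100 regroupings of the dose labels within genotypes, the labelled one included. The doses of a genotype share their controls, so their correlation is given beside a simulated one and beside values with split controls. Every count was set against 100 splits of the same arrays into groups of the same sizes, the labelled one included. The alternatives were another variance prior, array weights, a filter on dim transcript clusters, all transcript clusters of the table, centring of each array on its median, the replicate number as a block, the sex ratio of the pool as covariate, only the groups of the contrast, genotype differences averaged over shared doses instead of dose 0 alone, and leaving out each array in turn. A fit without 10 arrays, a covariate for the signal distribution of the arrays, and leaving out each array in the list tests were added after the data had been seen. No alternative background correction could be run, since the scanner values were not used here.

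The scripts were tested on simulated data with known changes. The comparison was CPO 0.75 against 0 in WT, with 50 changed genes of each size among 21789. The test recovered 54% of changes of 0.25 log2 units, 96% of changes of 0.5 and 100% of changes of 1 and of 2. All sizes were changed together, with noise drawn independently for each gene. A contrast with few or no changed genes has a stricter threshold after adjustment, and genes are correlated in the real data. These shares are therefore not the power of the contrasts with 0 calls. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the figures.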

Results

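Fetal brains from 60 dams were profiled, 1 array per dam, with 5 arrays in each of 12 labelled groups. PON1 is the blood enzyme that hydrolyses chlorpyrifos oxon (CPO), and its human Q192 and R192 forms differ in how efficiently they do so. The design asks whether repeated CPO in pregnancy changes gene expression in the fetal brain, and whether the mother's and fetus's PON1 status modifies that response. Any 2 arrays correlated between 0.9865 and 0.9984 over the 21789 tested transcript clusters. The median correlation was 0.9964 within labelled groups and also between them. No 2 arrays were identical. Array medians ran from 7.378 to 7.473 on the log2 scale.

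Pon1 did not follow the genotype labels. Its log2 signal was bimodal over the 60 arrays, low (at most 5.67) in 15 and high (at least 9.72) in 45, with nothing between. Of the 15 arrays labelled KO, 10 were low and 5 were high. Of the 45 labelled WT, Q-tg or R-tg, 40 were high and 5 were low. In arrays labelled KO the mean was 7.20 ± 2.54 (SD, n = 5) at dose 0, 5.28 ± 0.27 at 0.50 mg/kg/d and 8.24 ± 2.45 at 0.75 mg/kg/d. In arrays labelled WT it was 9.04 ± 2.06 at dose 0, 10.05 ± 0.06 at 0.75 and 9.06 ± 1.99 at 0.85. Those labelled Q-tg had 8.92 ± 2.28 at dose 0, 9.97 ± 0.10 at 0.75 and 8.99 ± 2.02 at 0.85. Those labelled R-tg had 9.97 ± 0.15, 9.06 ± 2.02 and 9.94 ± 0.08 in the same order. The 5 KO-labelled arrays with a high level were replicate 1 (10.04) and replicate 2 (9.91) at dose 0 and replicates 1 (10.14), 4 (10.03) and 5 (9.91) at 0.75. The 5 others with a low level were WT replicate 2 at dose 0 (5.36), WT replicate 5 at 0.85 (5.50), Q-tg replicate 3 at dose 0 (4.84), Q-tg replicate 1 at 0.85 (5.39) and R-tg replicate 3 at 0.75 (5.45).

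Genes beside Pon1 on chromosome 6 parted the arrays in the same way. Asb4, which encodes an ankyrin repeat protein, lay between 7.62 and 8.08 in the 15 arrays with low Pon1 and between 6.41 and 7.04 in the other 45. Calcr, the calcitonin receptor gene, lay between 7.76 and 8.12 against 7.19 to 7.60, and the imprinted gene Peg10 between 10.61 and 10.90 against 10.20 to 10.60. Of the 43 measured genes in the list of Pon1 and its neighbours, these 3 and Pon1 separated the arrays without overlap. Because 10 arrays carried a Pon1 level against their label, every group below is named by its label, and every direction between groups is one between labels. For the low arrays labelled Q-tg (2) and R-tg (1) this takes mouse Pon1 to be intact in the transgenic mice, which the labels do not state. The labels of dose have no such check among the genes measured.

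**Figure D1:**
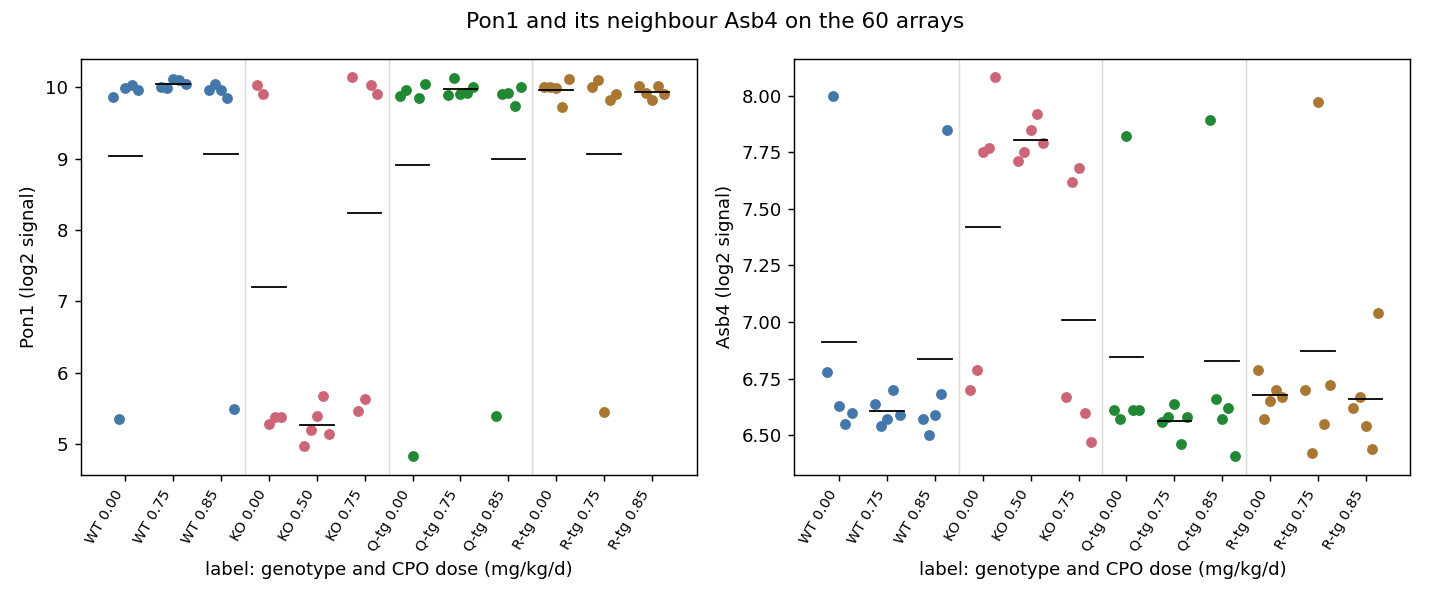
Log2 signal of Pon1 (left) and its neighbour Asb4 (right) on the 60 arrays, by labelled genotype and CPO dose in mg/kg/d; points are arrays in the order of their replicate number and bars are group means. Low Pon1 (at most 5.67) goes with high Asb4 (at least 7.62) in 10 arrays labelled KO and in 5 labelled WT, Q-tg or R-tg.

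The other paraoxonases and the cholinesterases, which organophosphates inhibit, had even levels. Over all 60 arrays the mean log2 signal was 7.61 ± 0.12 (SD) for Pon2, 6.72 ± 0.11 for Pon3, 8.88 ± 0.12 for acetylcholinesterase (Ache) and 6.72 ± 0.14 for butyrylcholinesterase (Bche). In the 8 CPO contrasts the log2 difference ran from -0.11 to 0.06 for Pon2 (SE 0.07), -0.10 to 0.14 for Pon3 (SE 0.07), -0.10 to 0.12 for Ache (SE 0.07) and -0.17 to 0.13 for Bche (SE 0.09). That of Pon1 ran from -1.93 to 1.05 (SE 1.02), which follows the arrays that went against their labels. None of the 5 genes passed the limma test in any of the 21 contrasts.

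Sex-linked genes and some genes of particular tissues differed widely between arrays. The X-linked RNA Xist, made in females, was low (at most 5.97) in 10 arrays, the Y-linked gene Eif2s3y was low (at most 4.59) in 6, and 44 arrays had both. Of the 5 arrays of a labelled group 3 to 5 had both, except in WT and in Q-tg at 0.75, with 1 each. At dose 0 these 2 labels had 4 each. Growth hormone (Gh) ran from 6.42 to 10.73 and was at least 8.84 in 21 arrays, with 0 to 3 of them in a labelled group, 1 in WT at dose 0 and 0 in WT at 0.75. Hoxa5, a gene of the hindbrain and spinal cord, ran from 5.78 to 8.28.

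**Figure D2:**
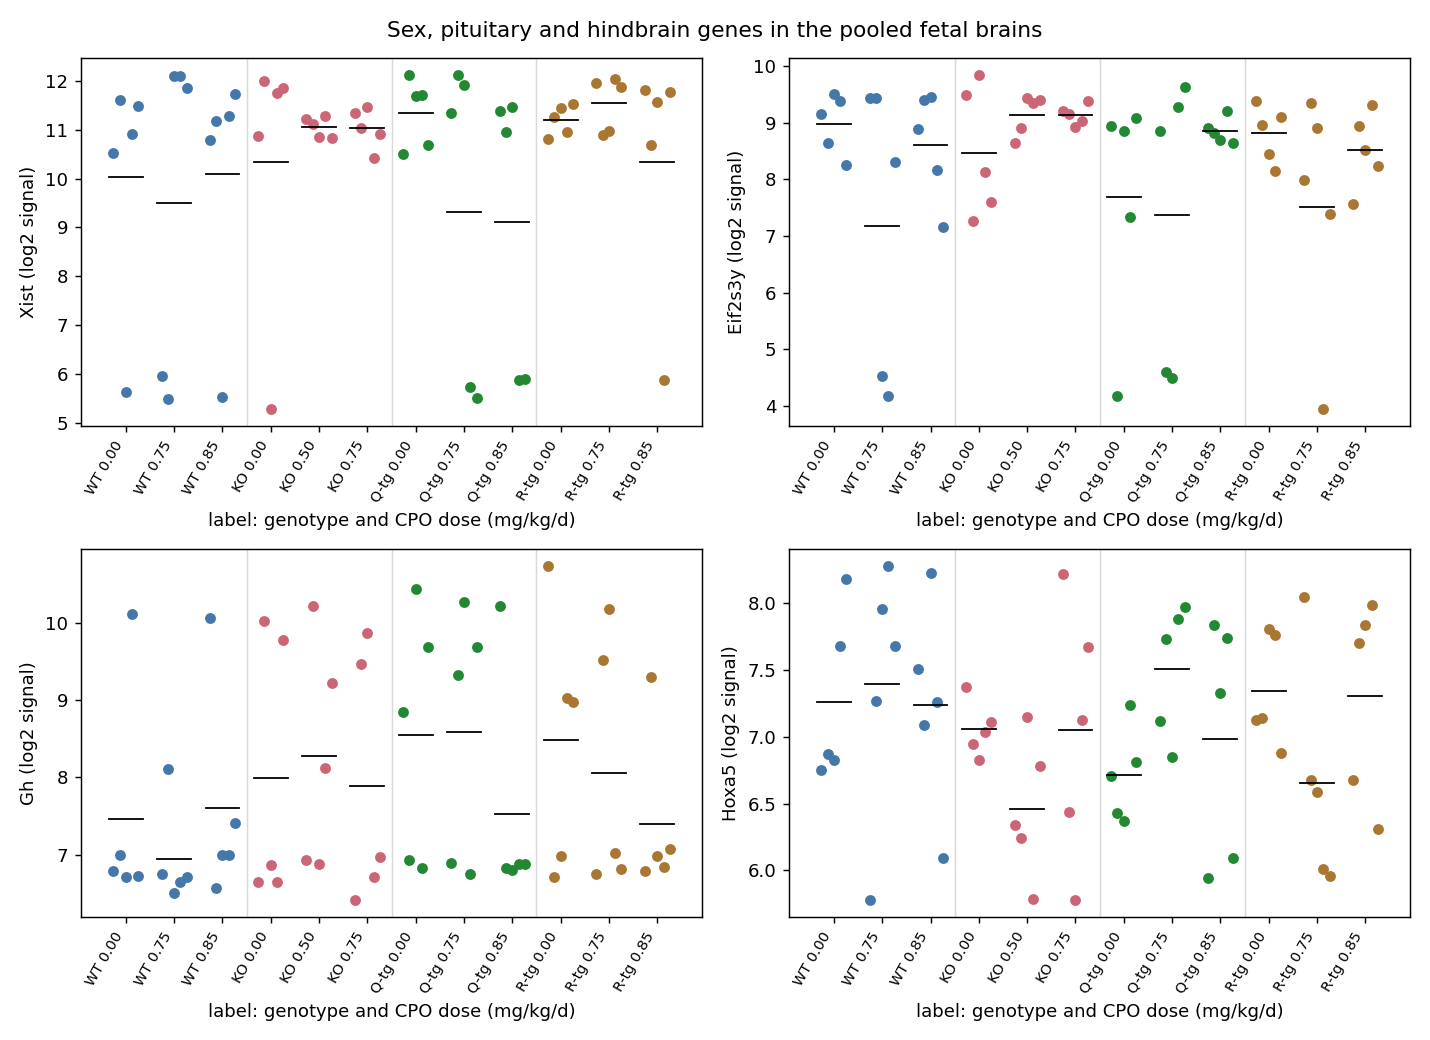
Log2 signal of Xist, the Y-linked gene Eif2s3y, growth hormone (Gh) and the hindbrain gene Hoxa5 on the 60 arrays, by labelled genotype and CPO dose in mg/kg/d; points are arrays in the order of their replicate number and bars are group means. Each of the 4 genes spans more than 2 log2 units over the arrays, with Gh from 6.42 to 10.73 and Hoxa5 from 5.78 to 8.28.

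In fetal brains labelled WT, CPO at 0.75 mg/kg/d was set against dose 0 to ask how a normal PON1 background responds. No gene passed. Ell2, which encodes an elongation factor of RNA polymerase II, had the smallest adjusted p, 0.064 in limma, with 7.17 ± 0.17 (SD, n = 5) at 0.75 and 6.83 ± 0.11 at dose 0, a log2 difference of 0.33 (SE 0.06). All 10 arrays lay beyond the other group's mean, which a choice by smallest p favours. At least 9 did for each of the 10 genes of smallest p at 0.85 as well. The next values were 0.27 for Pstpip2, -0.21 for the histone gene H4f16, -0.35 for the signalling adaptor Grap2, -0.68 for the kallikrein Klk1b11 and -0.25 for Rprl2. They were -0.27 for Batf3, -0.23 for Proser2, -0.34 for Kash5 and -0.25 for the muscle chaperone gene Unc45b, with adjusted p up to 0.369. Of these 10 genes, 4 were dim.

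Gene lists showed small differences in the same comparison, and with an estimated correlation 0 of them passed. Synapse genes passed as higher, 27 of 30, with a median of 0.055 log2 units (camera adjusted p = 0.000444) and an adjusted p = 0.864 with an estimated correlation. Shank1 (0.17), Homer1 (0.13), Grin2a (0.12) and Grin2b (0.11) had the largest differences, and 0 of the 30 passed when adjusted over the list alone or over all genes. Pituitary genes passed as lower, 14 of 15 with a median of -0.174 (adjusted p = 0.000444, and adjusted p = 0.864 with an estimated correlation), with -0.52 for Gh (SE 0.90), -0.28 for Tshb, -0.25 for Fshb and -0.22 for Lhx3. The Gh value rests on 1 array at dose 0, WT replicate 4 (10.11), as the other 4 were at 6.71 to 7.0 and those at 0.75 at 6.51 to 8.11. Genes of the hindbrain and spinal cord did not pass as a list (adjusted p = 0.0733). Its members Hoxc8 (-0.36), Hoxd8 (-0.27) and Hoxa7 (-0.24) did when adjusted over the list alone, and Hoxb7 (-0.18) did not. In all, limma called 0 of 21789 transcript clusters, and 2216 had an unadjusted p under 0.05 where chance gives 1089. The lower quartile of the signal moved with this group, 6.28 ± 0.06 at 0.75 against 6.36 ± 0.05 at dose 0. With array weights 39 passed, and with the lower quartile as covariate the unadjusted count was 1180.

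At 0.85 mg/kg/d no gene passed in the arrays labelled WT either. Among the 10 genes of smallest p, all higher, were the homocysteine methyltransferase gene Bhmt (0.36), the casein gene Csn3 (0.26), the guanylate-binding protein gene Gbp11 (0.30), Acmsd (0.27), Grid2ip (0.18) and Kir3dl2 (0.33). The others were the receptor genes Olfr739 (0.38), Olfr743 (0.28), Olfr136 (0.32) and Vmn1r45 (0.26). All 10 were dim. Cytosolic ribosomal protein genes passed as lower, 40 of 56 with a median of -0.025 (adjusted p = 0.000467, and adjusted p = 0.999 with an estimated correlation). Their largest values were -0.17 for Rpl14, 0.10 for Rpsa, -0.10 for Rps27l and -0.10 for Rpl21. limma called 0 transcript clusters, with 468 at an unadjusted p under 0.05, and 2 of these 10 arrays carried a Pon1 level against their label.

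KO-labelled brains were compared at 0.50 and 0.75 mg/kg/d against dose 0 to ask how fetuses without PON1 respond. At 0.50 the pseudogene Trim30e-ps1 (-0.49), the heart transcription factor Tbx20 (-0.40), Ccdc152 (-0.26), Tmem53 (-0.22), the CRH-binding protein gene Crhbp (-0.18) and Acsf2 (-0.15) had lower values. Spata17 (0.19), Vmn1r176 (0.33), the cytochrome P450 gene Cyp1a2 (0.28) and the placental gene Tpbpb (0.27) had higher ones. Their adjusted p was 1, and 7 of the 10 were dim. Hindbrain and spinal cord genes passed as lower, 19 of 22 with a median of -0.126 (adjusted p = 1.06e-05, and adjusted p = 0.843 with an estimated correlation). The largest values were -0.60 for Hoxa5 (SE 0.42), -0.42 for Hoxb5, -0.36 for Hoxa2 and -0.29 for Hoxb3, and 0 of the 22 passed when adjusted over the list alone or over all genes. limma called 0 transcript clusters at this dose, with 400 at an unadjusted p under 0.05.

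At 0.75 the KO-labelled brains had Cyp1a2, a target gene of the aryl hydrocarbon receptor, at 5.60 ± 0.08 (SD, n = 5) against 5.19 ± 0.15, a log2 difference of 0.41 (SE 0.09, limma adjusted p = 0.494). All 10 arrays lay beyond the other group's mean, as they did for all 10 genes of smallest p at 0.50, and the level was in the dim range. Adjusted over the list of xenobiotic metabolism alone, 1 of 30 genes passed, Cyp1a2 (adjusted p = 0.000675), while Cyp1b1 was at -0.13, Cyp2e1 at -0.12 and Mgst1 at -0.11. That list did not pass (camera adjusted p = 0.768). The higher Cyp1a2 values at 0.50 (0.28), at 0.75 and in KO minus WT below share the KO dose 0 arrays and are not independent. Among those arrays replicate 2, with a high Pon1 level, was far below the others for Cyp1a2 (4.93 against 5.23 to 5.32). The other 9 genes of smallest p were lower: Nop14 (-0.15), Zbtb14 (-0.18), Acsf2 (-0.18), Klra17 (-0.27), Vmn1r29 (-0.24), Cyyr1 (-0.19), Cyhr1 (-0.13), Pmfbp1 (-0.19) and the integrin gene Itga1 (-0.18). Vascular genes passed as lower, 22 of 24 with a median of -0.089 (adjusted p = 1.51e-05, and adjusted p = 0.955 with an estimated correlation), with -0.22 for Acta2, -0.16 for Pdgfrb, -0.13 for Cdh5 and -0.13 for Slco1c1. limma called 0 transcript clusters, with 631 at an unadjusted p under 0.05, and 5 of these 10 arrays had a high Pon1 level.

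Brains labelled Q-tg were compared with their dose 0 to ask how the human Q192 form modifies the response. At 0.75 mg/kg/d genes of the choroid plexus, the tissue that secretes cerebrospinal fluid, stood at higher values, among them the potassium channel Kcnj13 (0.30), Clic6 (0.24), Sostdc1 (0.23) and transthyretin (Ttr, 0.20). The list passed as higher, 12 of 16 with a median of 0.093 (adjusted p = 5.98e-06, and adjusted p = 0.246 with an estimated correlation), and 5 of its 16 genes passed when adjusted over the list alone but 0 over all genes. Astrocyte genes passed as higher, 20 of 20 with a median of 0.086 (adjusted p = 2.17e-10, and adjusted p = 0.340 with an estimated correlation). Aqp4 (0.32), Gfap (0.24), Aldoc (0.20) and Agt (0.20) had the largest differences, 0 of them passing over the list alone. Hindbrain and spinal cord genes also passed as higher, 18 of 22 with a median of 0.083 (adjusted p = 0.00254, and adjusted p = 0.747 with an estimated correlation), with 0.80 for Hoxa5 (SE 0.42), 0.48 for Hoxb5, 0.43 for Hoxa2 and 0.28 for Hoxb3. Cortex genes passed as lower, 13 of 17 with a median of -0.042 (adjusted p = 0.0153, and adjusted p = 0.747 with an estimated correlation). The other genes of smallest p were the matrix genes Fbln5 (0.26) and Npnt (0.16), Pamr1 (0.20), Gnl3l (0.15), Prps2 (0.24), Ctso (0.25) and Rsf1os2 (-0.28). limma called 0 transcript clusters, with 511 at an unadjusted p under 0.05. Q-tg replicate 3 at dose 0, a control here, had a low Pon1 level (4.84). It also had the lowest Ttr (12.24) and Hoxb5 (5.91) levels of all arrays.

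At 0.85 the Q-tg-labelled brains had Sesn2, a stress-induced regulator of growth signalling, at a log2 difference of 0.22 (SE 0.06), the melanocortin receptor gene Mc5r at 0.33 and the actin assembly gene Arpc1b at 0.23. Sesn2 was the 1 gene of 24 that passed when adjusted over the list of the unfolded protein and amino acid stress response alone (adjusted p = 0.00785), beside Ddit4 (0.15), Dnajb9 (-0.14) and Phgdh (0.10). Further genes of smallest p were Sval3 (0.29), Ikzf5 (0.18), Gab3 (0.24), Ddit4l (0.21), Riox1 (0.21), Spef2 (-0.28) and the muscle gene Trdn (-0.79). Their adjusted p was 0.999. Vascular genes passed as higher, 24 of 24 with a median of 0.086 (adjusted p = 1.49e-05, and adjusted p = 0.804 with an estimated correlation), with 0.16 for Esam, 0.14 for Mfsd2a, 0.13 for Vtn and 0.13 for Slco1a4. limma called 0 transcript clusters, with 842 at an unadjusted p under 0.05, and 2 of these 10 arrays had a low Pon1 level.

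For brains labelled R-tg the same contrasts ask how the human R192 form modifies the response. At 0.75 mg/kg/d the genes of smallest p had lower values, among them the brain transcription factor Rfx4 (-0.21), the growth factor gene Bmp7 (-0.17), Rhoj (-0.21), Ptpn3 (-0.23), Tns1 (-0.24), Akr1b10 (-0.26), Setd1b (-0.25), Acsf2 (-0.19) and Slc22a19 (-0.29). The exception was the limb gene Hoxd13 (0.34). R-tg replicate 1 at dose 0, a control here, lay far above the others of its group for Rfx4 (8.20 against 7.98 to 8.04). Axon guidance genes passed as lower, 28 of 34 with a median of -0.047 (adjusted p = 0.00178, and adjusted p = 0.871 with an estimated correlation). Netrin 1 (Ntn1, -0.19, SE 0.05) was the 1 gene that passed when adjusted over the list alone (adjusted p = 0.0279), beside Unc5c (-0.16), Efna5 (-0.15) and Sema3e (-0.14), and 0 passed over all genes. limma called 0 transcript clusters, with 1157 at an unadjusted p under 0.05 and a smallest adjusted p of 0.898.

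At 0.85 the R-tg-labelled brains had lower values of Sez6l (-0.18), Shisa6 (-0.26) and Sorcs1 (-0.14), which encode neuronal membrane proteins, of the organic anion transporter gene Slc22a8 (-0.21), and of Slco6c1 (-0.28), Cdc42ep1 (-0.24) and Fut10 (-0.19). The histone gene H4c6 (0.35), the Notch effector gene Hes7 (0.23) and Cfap43 (0.26) had higher ones. For Fut10 the control R-tg replicate 1 at dose 0 lay far above the others of its group (7.34 against 6.98 to 7.05). Synapse genes passed as lower, 28 of 30 with a median of -0.062 (adjusted p = 7.55e-07, and adjusted p = 0.935 with an estimated correlation). Bsn, a scaffold of the presynaptic active zone (-0.19, SE 0.06), was the 1 gene that passed when adjusted over the list alone (adjusted p = 0.0488), beside Shank1 (-0.19), Stx1a (-0.12) and Camk2a (-0.12). limma called 0 transcript clusters, with 1058 at an unadjusted p under 0.05 and a smallest adjusted p of 0.987.

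Averaging over labelled genotypes asks for a response that all share. At 0.75, over 40 arrays of 4 genotypes, the smallest p belonged to the bombesin receptor gene Brs3 (-0.16), Akr1c19 (-0.18), the splicing factor gene Rbm25 (0.08, SE 0.02), Cyyr1 (-0.10) and Cyrib (0.06). Pdzd9 (-0.13), Samt2b (0.26), Smim27 (-0.12), Wdr63 (0.08) and Casz1 (-0.10) followed, all at an adjusted p of 0.966. Heat shock genes passed as higher, 12 of 16 with a median of 0.017 (adjusted p = 0.0228, and adjusted p = 0.442 with an estimated correlation), with 0.11 for Chordc1, 0.06 for Dnajb1, -0.05 for Hspa1a and 0.05 for Hspa4l. At 0.85, over 30 arrays of WT, Q-tg and R-tg, Mc5r (0.21), Csn3 (0.18), Ddit4l (0.13), Srfbp1 (0.10), Kir3dl2 (0.19), Olfr727 (0.18), Ccnb3 (0.18), Slc22a14 (0.15), C1qtnf12 (0.09) and Meioc (0.15) had the smallest p, 6 of the 10 dim. Axon guidance genes passed as lower, 29 of 34 with a median of -0.021 (adjusted p = 1.64e-05, and adjusted p = 0.982 with an estimated correlation), with -0.05 for Nrp2, -0.04 for Slit2, -0.04 for Unc5b and -0.04 for Plxna4. limma called 0 transcript clusters in both averages, with 888 and 363 at an unadjusted p under 0.05.

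Comparing labelled genotypes at dose 0 asks what PON1 status does without exposure. Between KO and WT, Pon1 itself differed by -1.84 log2 units (SE 1.02, limma adjusted p = 0.999), with 2 KO-labelled arrays high and 1 WT-labelled array low. The other values of smallest p were -0.65 for Klk1b11, -0.48 for AF067061, 0.30 for Olfr1368, 0.15 for the transcription factor gene Tfcp2, 0.28 for Zfp330, 0.17 for Jakmip3, 0.16 for Aimp1, 0.18 for Pdlim7, 0.19 for Ccdc151 and 0.17 for the endocannabinoid synthase gene Dagla. Hindbrain and spinal cord genes passed as lower, 20 of 22 with a median of -0.050 (adjusted p = 0.00704, and adjusted p = 0.972 with an estimated correlation), with -0.20 for Hoxa5, -0.16 for Hoxb4, -0.14 for Hoxb2 and -0.11 for Hoxa7. limma called 0 transcript clusters, with 709 at an unadjusted p under 0.05. Without the 10 arrays whose Pon1 went against the label, 29 passed, 17 higher and 12 lower, from 3 arrays labelled KO and 4 labelled WT. They included Pon1 (-4.61, SE 0.09), Asb4 (1.23), Calcr (0.55), the DNA repair helicase gene Ercc2 (-0.59) and the antibacterial peptidoglycan recognition gene Pglyrp1 (-0.77). Of the 29, 8 lay on chromosome 6, where Pon1 is and 5.4% of the tested transcript clusters are, and 14 on chromosome 7, which holds 8.5% of those tested. These counts are of transcript clusters, and Rps13 on chromosome 7 is counted through more than 1. The chromosome is that of the named gene, and the position of the transcript cluster itself was not checked. The 10 arrays were chosen by their Pon1 level, so the calls of Pon1 and of every gene that parts the arrays as Pon1 does follow in part from that choice. Ercc2 and Pglyrp1 on chromosome 7 are among them, and so the shares of chromosomes 6 and 7 follow from it in part as well. Averaged over the doses the 2 labels share, instead of dose 0 alone, 6 of 15 values moved: Klk1b11 (from -0.65 to -0.14), Olfr1368 (to 0.15), Tfcp2 (to 0.05), Zfp330 (to 0.10), Jakmip3 (to 0.09) and Dagla (to 0.07).

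No gene passed between the transgenic labels and WT at dose 0, or between the 2 transgenic labels. Q-tg against WT had 0.34 for Fpr-rs6, 0.38 for Bhmt, -0.21 for the cell cycle phosphatase gene Cdc25c, 0.26 for Naip2, 0.11 for Mapkapk5, 0.30 for the carboxylesterase gene Ces3a, 0.19 for the neuropeptide Y receptor gene Npy5r, 0.21 for Olfr805, 0.17 for Olfr196 and 0.20 for Olfr1246. R-tg against WT had 0.23 for Atf1, 0.17 for Zmiz1, 0.20 for Rnf144b, 0.23 for Hmcn1, 0.16 for Clasrp, 0.20 for Tns1, 0.17 for Usp36, 0.28 for Gnat3, -0.21 for Tmprss11a and -0.28 for Olfr1220. R-tg against Q-tg had higher values of Fbln5 (0.28), Kcnj13 (0.32), Clic6 (0.25), Npnt (0.16), Atf1 (0.24), Sval3 (0.29), Pros1 (0.25) and Itih2 (0.25), and lower ones of Tceal5 (-0.22) and Ankrd60 (-0.29). In that last comparison astrocyte genes passed as higher, 20 of 20 with a median of 0.097 (adjusted p = 8.22e-06, and adjusted p = 0.734 with an estimated correlation), with Slc25a18 at 0.24, Aqp4 at 0.23, Agt at 0.16 and Apoe at 0.15. Oxidative phosphorylation genes passed as lower in Q-tg against WT, 56 of 72 with a median of -0.024 (adjusted p = 9.89e-05, and adjusted p = 0.835 with an estimated correlation), with -0.19 for Ndufb3, -0.10 for Ndufa11, -0.08 for Uqcrh and -0.08 for Ndufa2. It was 1 of 10 lists that passed there, 2 as higher and 8 as lower, and 0 did with an estimated correlation. Choroid plexus genes were lower, 13 of 16 with a median of -0.022 (adjusted p = 0.000697, and adjusted p = 0.835 with an estimated correlation), with -0.21 for Kcnj13, -0.18 for Ttr, -0.17 for Sostdc1 and -0.16 for Folr1. The Q-tg arrays at dose 0 are also the controls of Q-tg at 0.75, where Kcnj13 (0.30) and Ttr (0.20) were higher, so the 2 results are not independent. The same arrays enter R-tg against Q-tg. Its higher values of astrocyte genes, Kcnj13, Clic6, Fbln5 and Npnt are thus not independent of those in Q-tg at 0.75. Q-tg replicate 3 at dose 0 had the lowest Ttr level (12.24) of all arrays. R-tg replicate 1 at dose 0 lay far above the others of its group for Clic6, Pros1 and Usp36. Ribosomal protein genes passed as lower in R-tg against WT, 41 of 56 with a median of -0.025 (adjusted p = 2.85e-05, and adjusted p = 0.987 with an estimated correlation), with 0.21 for Rpsa, -0.16 for Rps15a, -0.11 for Rps19 and -0.09 for Rps12. limma called 0 transcript clusters in the 3 comparisons, with 362, 856 and 1183 at an unadjusted p under 0.05. Averaged over shared doses, values moved in all 3. They were 2 of 15 in Q-tg against WT, Cdc25c (to -0.08) and Mapkapk5 (to 0.01), and 9 of 15 in R-tg against WT, among them Atf1 (from 0.23 to 0.07), Tns1 (from 0.20 to 0.03), Usp36 (from 0.17 to 0.04) and Olfr1220 (from -0.28 to -0.06). In R-tg against Q-tg 10 of 15 did, among them Kcnj13 (from 0.32 to 0.01) and Fbln5 (from 0.28 to 0.03).

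Whether PON1 status modifies the CPO response was tested as a difference of differences. Ell2 was the 1 gene that passed in the 7 such contrasts. Its CPO 0.75 difference was 0.33 in WT-labelled and -0.15 in R-tg-labelled brains, a difference of -0.49 (SE 0.09, limma adjusted p = 0.038). Against the WT-labelled response Ell2 also stood at -0.42 in Q-tg (adjusted p = 0.526) and at -0.36 in KO (adjusted p = 0.635). In the same R-tg minus WT contrast Endou was at 0.53, the prostaglandin D synthase gene Hpgds at -0.42, Pstpip2 at -0.39, Rfx4 at -0.31, Tbx15 at -0.38, the DNA demethylation gene Tet3 at -0.35, Ptpn3 at -0.33, Batf3 at 0.38 and Cngb1 at 0.67, with adjusted p from 0.237 to 0.282. Leaving out the 10 arrays against their labels ended the Ell2 call at a difference of -0.52 (adjusted p = 0.0588). So did leaving out any 1 of 12 of the 20 arrays, or a variance prior with an intensity trend (adjusted p = 0.0685). The highest Ell2 level of the 60 arrays, 7.38, was in WT replicate 2 at 0.75, the array that alone had high Ibsp and Col1a1. Without it the difference was -0.43 (adjusted p = 0.121), and Ell2 in WT at 0.75 was at 0.28 (adjusted p = 0.489).

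The remaining differences of the CPO 0.75 response held no call. KO minus WT had the smallest p at Klk1b11 (1.02, SE 0.23), Cyp1a2 (0.56), Nop14 (-0.22), Reg2 (0.54), Unc45b (0.33), Tfap2e (0.42), the taste receptor gene Tas1r1 (0.44), the nicotinic receptor gene Chrna2 (0.40) and Cypt12 (0.40). Q-tg minus WT had it at Lctl (0.39), Mapkapk5 (-0.21), the angiotensin receptor gene Agtr2 (0.36), Tmprss11a (0.32), Hpgds (-0.33), the histone methyltransferase gene Kmt2d (-0.37), Cidea (0.31), Mpo (0.44) and Dglucy (0.27). R-tg minus Q-tg had it at Ptpn3 (-0.39), Fbln5 (-0.41), Npnt (-0.25), Vxn (-0.24), Kcnj13 (-0.48), Clic6 (-0.39), Klf5 (-0.20), Vmn1r84 (-0.47), Akr1b10 (-0.34) and Rbm47 (-0.37). Astrocyte genes passed as lower in R-tg minus Q-tg, 20 of 20 with a median of -0.186 (adjusted p = 7.49e-10, and adjusted p = 0.398 with an estimated correlation). Aqp4 (-0.49), Slc25a18 (-0.38), Apoe (-0.33) and Aldoc (-0.32) were among 10 of its 20 genes that passed when adjusted over the list alone, where 0 passed over all genes. In the dose 0 arrays of this contrast astrocyte genes were already higher in R-tg than in Q-tg (median 0.097). The lower values here rest in part on that control difference, also for Kcnj13, Clic6, Fbln5 and Npnt. limma called 0 transcript clusters in these 3 contrasts, with 1653, 485 and 1267 at an unadjusted p under 0.05.

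For the CPO 0.85 response the differences between labels were again uncalled. Q-tg minus WT had the smallest p at Ces3a (-0.54), Trdn (-1.08), the cell cycle checkpoint gene Sfn (-0.46), Rhox13 (-0.31), Mageb18 (-0.28), Mrpl17 (0.26), Gbp11 (-0.43), Adgb (-0.34), Bhmt (-0.51) and Olfr805 (-0.30). R-tg minus WT had it at H4c6 (0.50), Sez6l (-0.24), Fsip2 (-0.51), Uqcc2 (0.40), the retinoblastoma gene Rb1 (0.27), the condensin gene Smc4 (0.40), Macrod2 (-0.24), Prl7b1 (-0.39), Cers4 (-0.31) and Rp1 (-0.40). There, cell cycle genes passed as higher, 35 of 39 with a median of 0.074 (adjusted p = 1.05e-07, and adjusted p = 0.926 with an estimated correlation), with 0.26 for Top2a, 0.23 for Bub1, 0.22 for Hmmr and 0.19 for Kif11. R-tg minus Q-tg had it at the axon growth gene Sema7a (-0.26), Sval3 (-0.46), Trdn (1.29), Slc22a8 (-0.35), the microRNA processing gene Dgcr8 (-0.24), Zfp971 (0.64), Cfap43 (0.41), Btbd9 (-0.23), Macrod2 (-0.27) and the respiratory chain assembly gene Cox20 (0.39, SE 0.10). limma called 0 transcript clusters in the 3 contrasts, with 408, 1037 and 1786 at an unadjusted p under 0.05. In R-tg minus Q-tg array weights gave 118 calls, and leaving out R-tg replicate 5 at 0.85 gave 25.

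**Figure D3:**
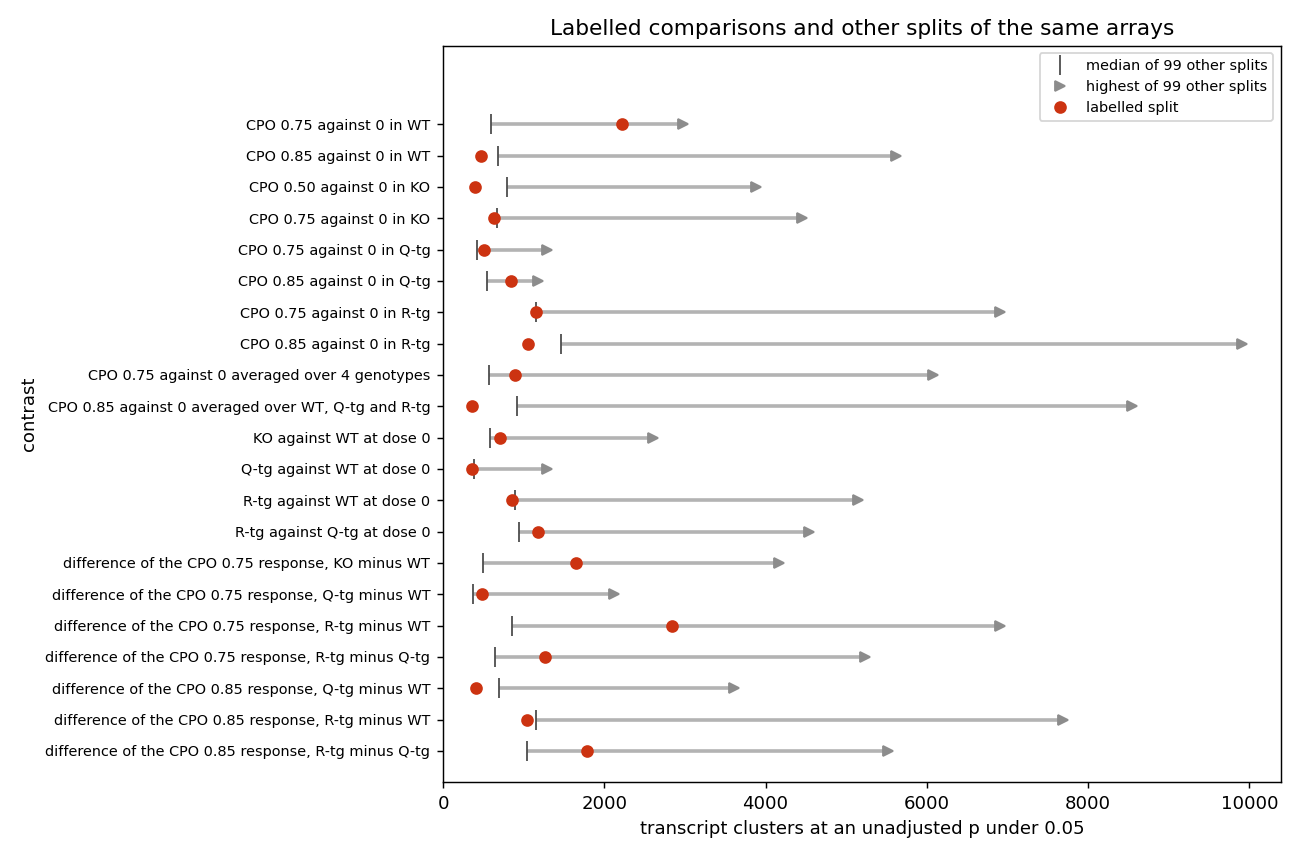
Number of transcript clusters at an unadjusted p under 0.05 in each of the 21 contrasts; red points are the labelled groups, grey lines run from the median to the highest of 99 other splits of the same arrays. The labelled counts lie between 362 and 2839, and in every contrast some other split gave more.

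Cholinergic genes, the direct context of a cholinesterase inhibitor, passed as a list in 0 of the 8 CPO contrasts. Their median lay between -0.062, in WT-labelled brains at 0.75, and 0.029, in Q-tg-labelled brains at 0.85. In the former the muscle-type nicotinic receptor genes Chrng (-0.30) and Chrnd (-0.20), Rapsn (-0.20) and Chrna9 (-0.18) had the largest values, and 0 of 31 passed when adjusted over the list alone. Serine hydrolases that organophosphates can bind passed as higher in Q-tg at 0.75, 34 of 41 with a median of 0.036 (adjusted p = 0.00357, and adjusted p = 0.747 with an estimated correlation), with 0.19 for Mgll, 0.17 for Nceh1, 0.12 for Ache and 0.11 for Bche. They also passed at 0.85, as higher in Q-tg (adjusted p = 0.0356) and as lower in R-tg (adjusted p = 0.0127), and the adjusted p with an estimated correlation was 0.927 and 0.935. The NRF2 oxidative stress list passed as higher in Q-tg at 0.75 alone (median 0.052, adjusted p = 0.00647, and adjusted p = 0.747 with an estimated correlation). Over the 8 CPO contrasts 53 of 328 list tests passed with the preset correlation, 25 as higher and 28 as lower. With an estimated correlation 0 passed, and with fry 0 passed.

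Agreement of the CPO 0.75 response between labelled genotypes was measured across genes, which are not independent replicates. The 6 correlations were -0.13 between WT and KO, 0.35 between WT and Q-tg, -0.31 between WT and R-tg, -0.09 between KO and Q-tg, 0.25 between KO and R-tg and -0.25 between Q-tg and R-tg. Their mean was -0.03, and 52 of 100 regroupings of the dose labels, the labelled one included, gave a mean as large. Only the pair of WT and Q-tg stood apart, with 3 of 100 regroupings as far from 0, a share not adjusted over the 6 pairs. Within a genotype both doses share controls. Their correlation was -0.05 in WT, 0.35 in KO, 0.55 in Q-tg and 0.61 in R-tg. Simulated unchanged groups that shared a simulated control gave 0.50, with noise drawn independently for each gene. Genes are correlated in the real data, and the spread without a response was not measured, so no departure from 0.50 is read from these values. The covariances were -0.0004, 0.0015, 0.0027 and 0.0034 against a simulated 0.0032. With the controls split, the correlations were -0.36 and -0.19 in WT, -0.29 and -0.12 in KO, 0.16 and 0.09 in Q-tg, and -0.18 and -0.07 in R-tg.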

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

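The tests of the Pon1 levels and of the small p-values in WT-labelled brains, the splits of the latter included, were chosen after the results were seen, while the other counts of splits were planned.

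Pon1 lay far from the other 4 arrays of its labelled group in 5 arrays: 4.84 in Q-tg replicate 3 at dose 0 (others 9.85 to 10.05), 5.39 in Q-tg replicate 1 at 0.85 (9.74 or more), 5.45 in R-tg replicate 3 at 0.75 (9.83 to 10.11), 5.36 in WT replicate 2 at dose 0 (9.87 to 10.03) and 5.50 in WT replicate 5 at 0.85 (9.85 to 10.05). A failure of the Pon1 probe set alone is argued against by 3 neighbour genes, Asb4, Calcr and Peg10, that part the same arrays without overlap. Exposure to CPO lowering Pon1 is argued against by 2 low arrays at dose 0, WT replicate 2 and Q-tg replicate 3, as far as their dose labels are right. A knockout colony of mixed genotype is argued against as the whole cause by the 5 low arrays labelled WT, Q-tg or R-tg. Labels attached to the wrong arrays may account for it. The 15 low arrays are as many as the 15 KO labels, as exchanges between KO and other labels would leave them. The match of 5 high KO-labelled arrays and 5 other low ones follows from that equality and adds nothing to it. Only KO-labelled arrays are taken here as low without exchanges, and the equality alone does not settle the cause. An order of the value columns with low Pon1 at all 15 KO places is described under other observations. Under it labels of dose and transgene would be displaced too, also in arrays whose Pon1 level matches their label.

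In WT-labelled brains at 0.75, 2216 transcript clusters had an unadjusted p under 0.05 and limma called 0. Of 100 splits of the same 10 arrays, the labelled one included, 6 gave as many, the highest other 2971, so chance cannot be excluded. With the sex ratio of the pool as covariate the count was 2218, which argues against a linear effect of that ratio. WT at 0.75 had 2 arrays with low Xist and 2 with low Eif2s3y, against 1 and 0 at dose 0. Pools of opposite sex can offset each other in the ratio, so another effect of the sex make-up stays open. The signal distribution of the arrays cannot be told apart from exposure, since the lower quartile differs between the groups (6.28 ± 0.06 against 6.36 ± 0.05), and with it as covariate the count was 1180. An effect of CPO therefore stays open beside it.

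Ell2 differed between labelled genotypes in its CPO 0.75 response, by -0.49 in R-tg minus WT (adjusted p = 0.038), the 1 call of that contrast. The highest Ell2 level, 7.38, was in WT replicate 2 at 0.75, which alone had high Ibsp and Col1a1, and without it the difference was -0.43 (adjusted p = 0.121). Of 100 splits, the labelled one included, 6 gave as many calls, the highest other 2000, so chance cannot be excluded. A split calling so many points to a structure of the samples.

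In the other contrasts limma called 0 transcript clusters. A count of 0 is reached by any split, 100 of 100 here, so these splits say nothing about chance in either direction. The highest count among the other splits was 0 in WT at 0.75, 144 in WT at 0.85, 2 in KO at 0.50, 18 in KO at 0.75, 1 in Q-tg at 0.75, 1 in Q-tg at 0.85, 1212 in R-tg at 0.75, 6139 in R-tg at 0.85, and 314 and 3667 in the averages at 0.75 and 0.85. At dose 0 it was 2 in KO against WT, 0 in Q-tg against WT, 3 in R-tg against WT and 1 in R-tg against Q-tg. For differences of the response at 0.75 it was 3 in KO minus WT, 0 in Q-tg minus WT and 3 in R-tg minus Q-tg, and at 0.85 it was 8 in Q-tg minus WT, 1713 in R-tg minus WT and 2 in R-tg minus Q-tg. Counts from 144 to 6139 where the labels gave 0 point to a structure of the samples. The first principal component, with 29.4% of the variance, correlated with the lower quartile of the arrays at r = -1.0, so the main axis between arrays is their signal distribution. Whether it underlies those counts was not tested. Of 100 regroupings of the dose labels, the labelled one included, 67 gave as many passing list tests as the real 53, the highest other 99. A mean correlation between genotypes as large as the real -0.03 came from 52 of 100, the highest other 0.32.

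Single arrays lay far from the other 4 of their group in 25 further cases, 30 with those of Pon1, of 381 groups tested, where chance gives about 1 in 20 groups, or 19. R-tg replicate 1 at dose 0 had 6 of them: Clic6 7.43 (others 7.10 to 7.17), Fut10 7.34 (6.98 to 7.05), Pon2 7.88 (7.52 to 7.57), Pros1 7.44 (7.08 to 7.14), Rfx4 8.20 (7.98 to 8.04) and Usp36 8.41 (8.23 to 8.25). Others in R-tg were Aqp4 8.41 in replicate 2 (8.65 to 8.72), Fbln5 8.20 (7.93 or more, all lower than 8.20) and H4c6 8.65 (9.18 to 9.28) in replicate 4 at dose 0. At 0.85 R-tg had H4c6 9.70 in replicate 1 (9.38 to 9.43), Fut10 6.80 in replicate 3 (6.90 to 6.93) and Hes7 7.26 in replicate 5 (7.46 to 7.52). KO at dose 0 had Klra17 3.48 in replicate 1 (3.83 to 3.89), Cyp1a2 4.93 in replicate 2 (5.23 to 5.32), Nop14 8.36 in replicate 4 (8.40 to 8.42) and Itga1 7.86 in replicate 5 (7.98 to 8.02). Exposed KO had Tpbpb 3.12 in replicate 2 at 0.50 (3.34 to 3.40) and Pon3 6.50 in replicate 2 at 0.75 (6.70 to 6.77). Q-tg had Ctso 8.25 in replicate 5 at dose 0 (7.77 to 7.88) and Pon2 7.46 in replicate 1 at 0.75 (7.60 to 7.64). WT at dose 0 had H4f16 8.81 in replicate 2 (9.01 to 9.08), Ndufa2 8.81 in replicate 4 (9.05 to 9.14) and Rps12 10.66 in replicate 5 (10.54 to 10.57). WT at 0.75 had Proser2 7.39 in replicate 2 (7.45 to 7.46) and Batf3 6.59 in replicate 3 (6.84 to 6.86).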

How the results depend on the processing

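The fit without the 10 arrays whose Pon1 went against the label, the lower quartile covariate and leaving out arrays in the list tests were chosen after the results were seen. The call of Ell2 in the CPO 0.75 response of R-tg minus WT ended, at a count of 0, with a trended and robust variance prior, with all transcript clusters of the table, with arrays centred on their median, with the replicate number as block, with the lower quartile as covariate, without the 10 arrays, and with only the groups of the contrast. Over the alternatives other than leaving out single arrays its log2 difference lay between -0.43 and -0.52 and its adjusted p ran from 0.00902 to 0.26. Array weights gave 39 calls in WT at 0.75, 118 in the CPO 0.85 response of R-tg minus Q-tg, 2 in the CPO 0.75 response of R-tg minus WT, and 1 each in R-tg at 0.85, in the average at 0.85, in R-tg against Q-tg at dose 0 and in the CPO 0.75 response of R-tg minus Q-tg. WT at 0.75 gave 1 call above the dim level and 1 with the sex ratio as covariate. The CPO 0.85 response of R-tg minus Q-tg gave 9 calls over all transcript clusters, 2 with the lower quartile as covariate and 1 without the 10 arrays. R-tg against WT at dose 0 gave 1 with the lower quartile. Without the 10 arrays KO against WT gave 29, and 1 of the paraoxonase and cholinesterase genes passed, Pon1, which follows from how the arrays were chosen. Genotype differences averaged over shared doses gave 0 calls in the 4 contrasts at dose 0, and of 60 values of genes 27 moved and 33 stayed the same. Without the 10 arrays 7 further values of genes moved, with array weights 3 and with the lower quartile 1. Of the list tests 0 passed with an estimated correlation and 0 with fry. Leaving out each array in turn gave 0 to 1 in WT at 0.75 (1 without WT replicate 1 or replicate 5 at 0.75), 0 to 1 in R-tg against WT at dose 0 (1 without WT replicate 1), and 0 to 25 in the CPO 0.85 response of R-tg minus Q-tg (25 without R-tg replicate 5 at 0.85). It gave 0 to 1 in the CPO 0.75 response of R-tg minus WT, with 0 without R-tg replicates 1, 2, 4 or 5 at dose 0 or 1, 2 or 4 at 0.75, or WT replicates 1 or 2 at dose 0 or 2, 3 or 4 at 0.75. It gave 49 to 62 passing list tests, mean correlations of -0.07 to 0.02 between genotypes and 0.31 to 0.45 between doses, and 0 in the other contrasts. No called value changed sign, while uncalled ones did, such as Bche (0.13 to -0.02) and Pon1 (0.92 to -0.03) in R-tg against WT averaged over shared doses. Apart from the sample choice behind Pon1 the cause was not tested. Replicate numbers do not pair the samples, since 8 of 60 arrays correlated best with their own number. Signal over background limits the dim transcript clusters, as 15611 of 21789 lay above the olfactory receptor level of 6.54.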

Other observations

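The tests in this part were all chosen after the values were seen.

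An order of the value columns other than the listed one was looked at for the Pon1 levels, without a decision. After the places of the low arrays were known, 3 orders were tried, each taking the arrays as numbered by group and replicate. The plain text order of the numbers (1, 10, 11 and so on) put low Pon1 at 9 of the 15 places of the KO numbers, against 10 under the labels. The same order moved by 1 place gave 15 of 15, and so did the text order of numbers followed by a sign that sorts after the digits, which puts 10 to 19 before 1. These 2 were picked because they match, and the labels name no numbered array files, so no chance is given and neither order is preferred. Yet the low arrays stand at value columns 1 to 6, 11, 22, 33, 44, 55 and 57 to 60. These are exactly the places of the KO numbers in both orders, a pattern that exchanges of single arrays have no reason to make. A displaced order of the columns therefore cannot be set aside, though the cause is not decided. No array was reassigned and no comparison was repeated in another order. If the listed order is wrong, dose and transgene labels may be displaced as well, for which no gene measured here gives a check.

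The tissue in the pools may have varied. Pituitary tissue in some pools is a candidate source of the Gh range, 6.42 to 10.73. The pituitary hormone genes Cga and Pomc correlated over the 60 arrays (Pearson r = 0.76, Spearman 0.76, 0.76 without the 2 farthest arrays). Gh itself was not part of that test, so it does not show where the Gh range comes from. A varying amount of hindbrain or spinal cord may lie behind the Hoxa5 range, 5.78 to 8.28, since Hoxa5 and the glycine transporter gene Slc6a5 correlated (Pearson r = 0.95, Spearman 0.95, 0.94 without the 2 farthest). Both had a permutation p of 1e-05, the smallest the permutations can give, also after adjustment. Dissection and a biological difference in these cells were not told apart.

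WT replicate 2 at 0.75 alone had high levels of Bpifb9b (10.32, next array 4.67), Ibsp (9.69, next 6.48), Col1a1 (10.66, next 9.03), Bpifa1 (9.0, next 6.79), Reg3g (7.64, next 5.49) and Cyp2g1 (7.71, next 6.64). Marchf1 was 7.11 in KO replicate 1 at dose 0 and 7.26 in R-tg replicate 1 at 0.75, and at least 7.99 in the other 58 arrays. Mid1 ran from 8.37 to 10.71, with 16 arrays at or above 9.81 and 44 at or below 9.39. The 15 arrays with low Pon1 were among the 16, and the remaining one was R-tg replicate 5 at dose 0 (10.02). Pglyrp1 (7.15 to 7.62 against 7.86 to 8.35) and Ercc2 (7.91 to 8.23 against 8.50 to 8.93), both on chromosome 7, parted the same 15 arrays from the other 45 without overlap. These genes, which are not on the chromosome of Pon1, were chosen after their values were seen.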
